A study of Mus musculus with 41 samples.

How the data were processed

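The deposited gene tables hold counts of reads per gene, and the exon tables counts of reads per exon part, per the labels. Reads had been processed with CASAVA 1.8.2, aligned with STAR to mm10 and counted with HTSeq, per the submitters' processing notes; the versions of STAR and HTSeq, the annotation and the strand of counting are not given in the sources used here. Antisense and overlapping transcripts were therefore not told apart. Per the labels' protocols, CA1 was microdissected and a cube of liver taken, each was snap-frozen, RNA was extracted with Tri reagent and treated with DNase, and 500 ng was used for each library. Old mice drank water with 18 g cyclodextrin per L, with or without 0.67 g SAHA per L, for 4 weeks.

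Gene identifiers numbered 37315 in CA1 and 38355 in liver, of which 95.0% and 95.4% had a symbol in GENCODE M21 (GRCm38, the assembly also called mm10), and coordinates are from that release. The liver tables carry 5 counter lines that are not genes, which were left out: reads without a feature made up 7.63% to 13.2% and ambiguous reads 1.16% to 2.23%, while alignments that were not unique came to 35.4% to 49.2%. Library totals over genes were 17.9M to 29.7M in CA1 and 16.6M to 27.3M in liver. Liver old vehicle library 7 is old by its title and source but has an age entry of 3 months; on the first principal component of the 1000 most variable genes it stood at 33.6, where young libraries ran from -41.1 to -35.8. It was kept as old, and without it 2098 genes passed for age and 1414 for SAHA.

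Genes were tested with edgeR 4.0.16 in R 4.3.3, with 1 quasi-likelihood model of the 3 groups for each tissue, TMM scaling, filterByExpr (lowest count 10, lowest total 15) and Benjamini-Hochberg adjustment over all genes tested. A gene passed at an adjusted p under 0.05, and its standard error is the log2 fold change divided by the square root of F. Exon part use was tested with diffSpliceDGE of edgeR over genes with at least 2 parts, and differences between tissues with 1 model of both tissues. These choices were made before the data were examined. DESeq2 1.42.0, limma 3.58.1 and sva 3.50.0 gave the alternatives, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for tables and plots.

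Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, where at least 3 members were tested. The 29 lists of CA1 and 31 of liver shared histone deacetylases, histone acetyltransferases, MHC class I presentation, MHC class II presentation, interferon response, complement, endoplasmic reticulum chaperones, cytosolic heat shock, oxidative phosphorylation, cholesterol synthesis, collagens and extracellular matrix, cell cycle, p53 targets and senescence, circadian clock, T and NK cell markers, B and plasma cell markers, red blood cell markers and immediate early genes. CA1 also had synapse, microglia, astrocyte, oligodendrocyte, oligodendrocyte precursor, brain endothelial and mural, choroid plexus, CA1 pyramidal, CA3 and CA2, dentate granule and newborn neuron, and interneuron markers. Liver also had hepatocyte, Kupffer cell and macrophage, liver endothelial and cholangiocyte markers, acute phase, cytochrome P450 drug metabolism, conjugation and NRF2 targets, male-biased and female-biased liver genes, fatty acid synthesis, fatty acid oxidation and PPARA targets, bile acid synthesis and transport, and gluconeogenesis.

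Genes named for a comparison were set by a rule: the 8 largest rises and 8 largest falls among passing genes with a mean log2 CPM of at least 2, leaving out predicted genes, clone names, pseudogenes and antigen receptor segments, and for each list up to 4 passing members by smallest p, of which 2 are given, or 1 member that did not pass. For opposite changes the 10 genes with the smallest larger p were taken and 5 are given. Exon part use and tissue differences named 5 genes each. No genes were selected for old SAHA against young vehicle, where genes named for age are given again. Some genes that the rule selected are not reported here.

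The GC trend of each library was a spline with 4 degrees of freedom of log2 counts on the GC content of the gene, which 98.8% of tested CA1 genes and 99.2% of tested liver genes had, and was removed as an offset. Its groups were compared by exact tests over all splits of the libraries. This step and the clock, immune, red blood cell and choroid plexus scores were chosen after seeing the data. The clock score of a library was its position on the main axis of the 13 clock genes within groups.

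Simulated counts with 50 genes changed at each fold size were run through the same tests. At folds of 1.5, 2 and 4, CA1 recovered 40, 48 and 50 for age (15 unchanged genes passed of 16483 genes run), 40, 46 and 49 for SAHA (5 passed) and 40, 45 and 48 for old SAHA against young (10 passed). Liver recovered 18, 39 and 46 for age (3 passed of 13916), 25, 41 and 50 for SAHA (6 passed) and 22, 41 and 49 for old SAHA against young (7 passed). Exon part use recovered 33, 48 and 48 in CA1 (25 passed) and 9, 35 and 50 in liver (14 passed), and the tissue difference 22, 36 and 49 (5 passed). A changed list was recovered in each tissue at a fold of 1.5. A simulated GC trend in CA1 made 517 unchanged genes pass when left in and 0 when removed.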

Results

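Gene counts of the CA1 subregion of the hippocampus and of liver were compared between C57B/6JRj mice of 3 months (young) and of 20 months (old) that drank vehicle, per the labels. Further mice of 20 months drank the histone deacetylase inhibitor SAHA (vorinostat) for 4 weeks. The 41 libraries comprised 20 of CA1 (8 young vehicle, 6 old vehicle, 6 old SAHA) and 21 of liver (6 young vehicle, 7 old vehicle, 8 old SAHA). Each tissue gave 3 differences: old vehicle against young vehicle (age), old SAHA against old vehicle (SAHA), and old SAHA against young vehicle (the difference left after SAHA). Brackets after a gene give its log2 fold change ± standard error and its Benjamini-Hochberg adjusted p from an edgeR quasi-likelihood test, and group values are mean ± SD in CPM, counts scaled to the library total. Gene lists were tested with camera, and brackets after a list give the number of its genes that passed in its direction, the same number adjusted over the list alone, the median log2 fold change and the adjusted p, or for lists that did not pass the adjusted p only. The labels give each library a number but do not state separate animals, so the p-values measure the spread between libraries. APP/PS1 mice, named in the series title, are not analysed here.

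Complement, antigen presentation and interferon genes rose with age in CA1. C4b (2.46 ± 0.20, 1.78e-07), which encodes complement component C4 (ENSMUSG00000073418, chr17:34728380-34743882), rose from 25.7 ± 3.72 CPM in young vehicle (n = 8) to 141 ± 35.1 CPM in old vehicle (n = 6). Genes of antigen presentation rose with it, Tap1 (1.11 ± 0.18, 9.20e-04) and Tap2 (0.77 ± 0.13, 0.00136), the peptide transporter of MHC class I, and H2-DMa (0.36 ± 0.10, 0.0362) of MHC class II. Microglial genes followed, the lysosomal Cd68 (0.71 ± 0.09, 8.61e-05) and Ctss (0.79 ± 0.10, 8.61e-05), the complement gene C1qa (0.92 ± 0.12, 1.28e-04), the lysozyme gene Lyz2 (1.52 ± 0.32, 0.00882) and the inhibitory receptor gene Lag3 (1.29 ± 0.11, 5.78e-07). The astrocyte genes Gfap (0.91 ± 0.11, 4.90e-05) and S100b (0.33 ± 0.07, 0.00757) rose too. Interferon-induced genes were higher, Irf7 (1.79 ± 0.31, 0.00210), Ifit3 (1.23 ± 0.29, 0.0184), Ifit1 (1.43 ± 0.38, 0.0311), Oasl2 (1.55 ± 0.41, 0.0311) and the secreted galectin ligand Lgals3bp (1.11 ± 0.26, 0.0180). The class I gene H2-Q4 (1.27 ± 0.28, 0.0108) was higher as well. The Ifit and H2-Q families hold close copies, so which copy the reads of Ifit3 and H2-Q4 came from is uncertain.

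Falls in old CA1 included Gpr17 and 3 activity-induced genes. Gpr17 (-1.0 ± 0.09, 5.38e-07), a receptor of precursors committed to the oligodendrocyte lineage (ENSMUSG00000052229, chr18:31942997-31949636), fell from 67.7 ± 7.80 to 33.9 ± 3.60 CPM. The activity-induced Fos (-0.98 ± 0.24, 0.0206), Arc (-0.70 ± 0.18, 0.0297) and Dusp1 (-0.44 ± 0.10, 0.0199) fell as well. Further falls were of the ubiquitin ligase genes Rnf152 (-0.83 ± 0.16, 0.00528) and Rnf122 (-0.74 ± 0.14, 0.00375), the carbonic anhydrase-related Car8 (-0.68 ± 0.13, 0.00505), the regeneration-associated Nrep (-0.62 ± 0.16, 0.0234) and the protocadherin Pcdh18 (-0.55 ± 0.13, 0.0156). Lower values also came from Rrm2 (-0.89 ± 0.20, 0.0127), which encodes a ribonucleotide reductase subunit, the p53 target Trp53inp1 (-0.34 ± 0.05, 4.17e-04), the clock repressor Nr1d2 (-0.21 ± 0.04, 0.00748) and the deacetylase gene Hdac2 (-0.17 ± 0.04, 0.0127). Chaperone genes were slightly lower, Pdia6 (-0.15 ± 0.04, 0.0168), Hsph1 (-0.19 ± 0.05, 0.0318) and Hspa8 (-0.14 ± 0.04, 0.0420), as was Atp5g1 (-0.23 ± 0.04, 0.00460) of ATP synthase. Srebf2 (0.22 ± 0.05, 0.00828), the regulator of cholesterol synthesis, and the matrix gene Sparc (0.23 ± 0.06, 0.0437) were slightly higher.

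Of 16554 genes tested, 891 passed an adjusted p of 0.05 (532 higher, 359 lower), 81 of them by more than 2-fold, with a median absolute log2 fold change of 0.32. 28 of the 40 passing genes named here passed whichever 1 library was left out. The others reached an adjusted p of 0.0633 (Arc), 0.0503 (Dusp1), 0.0503 (Fos), 0.0806 (H2-DMa), 0.0921 (Hspa8), 0.0691 (Hsph1), 0.109 (Ifit1), 0.0595 (Ifit3), 0.0580 (Lgals3bp), 0.0607 (Nrep), 0.131 (Oasl2) and 0.0965 (Sparc) without 1 library. Such losses, counted in brackets, came without old vehicle libraries 1 (2), 2 (2), 3 (4), 4 (7), 5 (11), 6 (5) and young libraries 2 (3), 3 (4), 4 (5), 5 (7), 6 (4), 7 (1), 8 (2). Old vehicle library 5 stood far above the others for the interferon-induced Oasl2 (34.1 CPM, next 6.80), Irf7, Ifit3 and Lgals3bp. Without it the fold changes were 0.65 for Oasl2, 1.03 for Ifit1, 0.82 for Ifit3, 0.85 for Lgals3bp and 1.28 for Irf7, of which Irf7 passed. The number of passing genes was 578 without old vehicle library 3, 445 without 4, 465 without 5 and 492 without 6, and 547, 513 and 575 without young libraries 4, 5 and 6.

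Among the gene lists, microglia markers (11 of 12, 12, 0.52, 2.23e-16), MHC class I presentation (8 of 11, 10, 0.77, 4.63e-09) and interferon response (9 of 15, 12, 1.23, 4.20e-07) rose with age in CA1. Complement (4 of 11, 5, 0.44, 1.92e-05) and astrocyte markers (2 of 11, 4, 0.16, 0.0175) rose too. Endoplasmic reticulum chaperones (1 of 17, 3, -0.09, 4.46e-05), p53 targets and senescence (1 of 7, 2, -0.12, 0.0175) and cell cycle (1 of 8, 1, -0.27, 0.0363) fell. None of these passed under the stricter test (adjusted p = 0.177 to 0.392 with an estimated correlation). Of the astrocyte genes 1 was lower. Without old vehicle library 5 the rising lists still passed (interferon response 8.43e-06) and the cell cycle list did not (0.0544). Neuronal lists did not pass: synapse (0.376), immediate early genes (0.107), CA1 pyramidal markers (0.376), CA3 and CA2 markers (0.684), dentate granule and newborn neuron markers (0.994), interneuron markers (0.994). Nor did those of other cells: oligodendrocyte markers (0.376), oligodendrocyte precursor markers (0.260), brain endothelial and mural markers (0.954), choroid plexus markers (0.954), red blood cell markers (0.376). Lists of metabolism, matrix and chromatin gave oxidative phosphorylation (0.728), cholesterol synthesis (0.684), collagens and extracellular matrix (0.954), cytosolic heat shock (0.312), circadian clock (0.376), MHC class II presentation (0.101), histone deacetylases (0.684), histone acetyltransferases (0.954). The test, median and mean differed in sign for histone deacetylases, histone acetyltransferases, collagens, endothelial and mural, dentate and interneuron markers. T and NK cell markers and B and plasma cell markers, with 2 measured genes each, were not tested. Genes that did not pass were Kat6b (0.07 ± 0.05, 0.356), Lck (0.23 ± 0.13, 0.304), Jchain (0.56 ± 0.61, 0.633), Hbb-bt (-0.49 ± 0.24, 0.225), Shank1 (0.25 ± 0.08, 0.0711) and Mal (-0.34 ± 0.14, 0.161). Nor did Kcnj8 (0.29 ± 0.09, 0.0638), Prlr (-0.34 ± 0.40, 0.660), Pou3f1 (0.39 ± 0.13, 0.0877), Coch (-0.97 ± 0.42, 0.169), Sox11 (-0.47 ± 0.19, 0.146) and Sst (0.27 ± 0.09, 0.0829) pass.

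**Figure D1:**
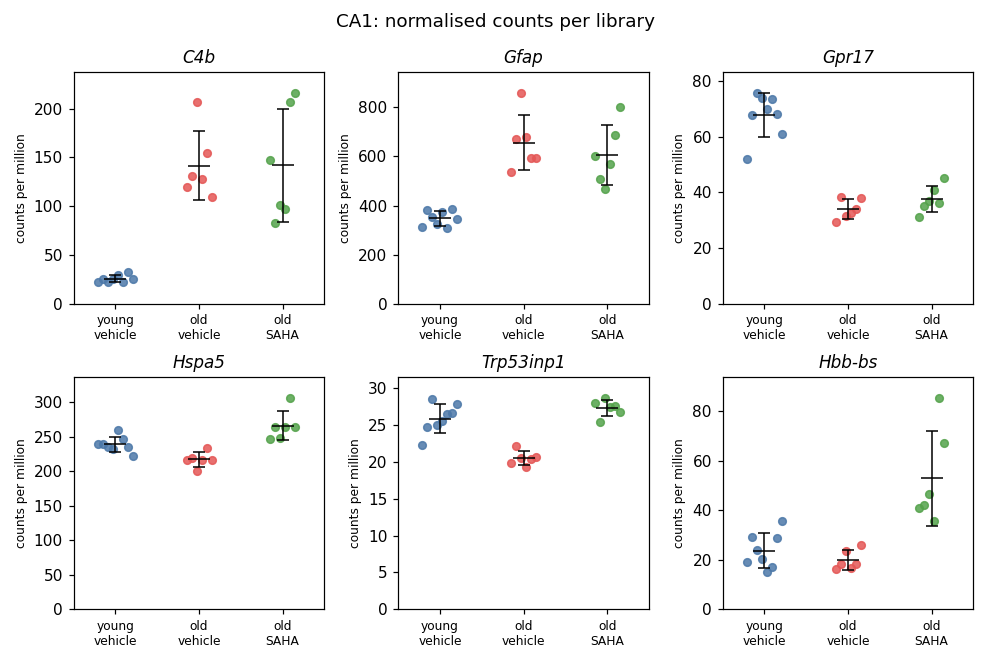
CPM of 6 genes in CA1 of young vehicle (n = 8), old vehicle (n = 6) and old SAHA (n = 6). Points are libraries and black marks are mean ± SD.

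In old CA1, SAHA was accompanied by higher values of chaperone and haemoglobin genes. Hspa5 (0.29 ± 0.05, 0.00566), which encodes the main chaperone of the endoplasmic reticulum (ENSMUSG00000026864, chr2:34771970-34777547), rose from 217 ± 10.6 CPM in old vehicle (n = 6) to 266 ± 21.2 CPM in old SAHA (n = 6). Its partner Dnajc3 (0.33 ± 0.07, 0.0146) rose with it. Trp53inp1 (0.42 ± 0.05, 0.00207), a p53-induced regulator of autophagy (ENSMUSG00000028211, chr4:11156431-11174379), rose from 20.5 ± 0.955 to 27.3 ± 1.14 CPM, and Mdm2 (0.16 ± 0.04, 0.0378), which encodes the p53 ubiquitin ligase, rose with it. The beta-globin genes Hbb-bt (1.68 ± 0.25, 0.00566) and Hbb-bs (1.42 ± 0.22, 0.00566) were higher, the latter at 52.9 ± 19.2 against 19.8 ± 3.98 CPM, and their near-identical sequences leave the copy uncertain. Higher as well were the lipid droplet gene Plin4 (1.18 ± 0.20, 0.00566), the junction gene Perp (1.04 ± 0.30, 0.0432) and the astrocyte connexin Gja1 (0.18 ± 0.04, 0.0201). So were the monooxygenase gene Fmo2 (1.03 ± 0.22, 0.0136) and the sulfotransferase gene Sult1a1 (0.95 ± 0.18, 0.00778).

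Genes lower with SAHA in CA1 included Grin1 (-0.34 ± 0.07, 0.0112), the obligate NMDA receptor subunit, the synaptic Prr7 (-0.82 ± 0.24, 0.0495) and Lrfn4 (-0.61 ± 0.12, 0.00858) and the microtubule genes Map1s (-0.62 ± 0.14, 0.0141) and Tpgs1 (-0.73 ± 0.17, 0.0183). The linker histone H1fx (-0.68 ± 0.17, 0.0231), the matrix gene Tnc (-0.82 ± 0.23, 0.0389), the cytokine receptor Crlf2 (-0.68 ± 0.17, 0.0257) and Klhdc9 (-0.62 ± 0.12, 0.00738) fell too. Hdac5 (-0.24 ± 0.06, 0.0376), a class IIa deacetylase, and the acetyltransferases Kat5 (-0.15 ± 0.04, 0.0364) and Kat2a (-0.15 ± 0.04, 0.0364) were slightly lower. Srebf2 (-0.27 ± 0.05, 0.00738), Uqcrc1 (-0.20 ± 0.05, 0.0240) of respiratory complex III, the precursor marker Cspg4 (-0.30 ± 0.08, 0.0230) and the clock repressor Nr1d1 (-0.18 ± 0.04, 0.0211) fell too. 3 of the largest rises rested on few libraries: Ttr (7.75 ± 1.74, 0.0156) and Aqp1 (3.95 ± 1.0, 0.0257), both made by choroid plexus, and Lars2 (2.51 ± 0.64, 0.0257), the mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, chr9:123366927-123462666). Without old SAHA library 5 the fold changes were 0.87 for Ttr (adjusted p = 0.381), 0.65 for Aqp1 (adjusted p = 0.268) and 0.62 for Perp (adjusted p = 0.0947). Without old SAHA library 6 that of Lars2 was 1.45 (adjusted p = 0.0688).

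SAHA against vehicle in old CA1 gave 913 passing genes of 16554 (299 higher, 614 lower), 25 of them by more than 2-fold, with a median absolute log2 fold change of 0.26. 17 of the 34 passing genes named here passed whichever 1 library was left out. The others reached an adjusted p of 0.268 (Aqp1), 0.0714 (Crlf2), 0.0707 (Cspg4), 0.0524 (Gja1), 0.0641 (H1fx), 0.103 (Hdac5), 0.0967 (Kat2a), 0.118 (Kat5), 0.0688 (Lars2), 0.0754 (Mdm2), 0.0742 (Nr1d1), 0.0972 (Perp), 0.125 (Prr7), 0.117 (Tnc), 0.0562 (Tpgs1), 0.381 (Ttr) and 0.0835 (Uqcrc1) without 1 library. Such losses, counted in brackets, came without old SAHA libraries 1 (3), 2 (10), 3 (2), 4 (14), 5 (9), 6 (3) and old vehicle libraries 1 (10), 2 (2), 3 (2), 4 (15), 5 (13), 6 (15). The number of passing genes was 534, 341, 472 and 278 without old vehicle libraries 1, 4, 5 and 6, and 514 and 291 without old SAHA libraries 2 and 4.

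The genes that passed for SAHA in CA1 differed in base composition. Median GC content was 43.9% for those that rose, 58.3% for those that fell and 49.8% over all genes tested. Each library's counts also ran with GC content, by 0.0777 ± 0.0336 log2 per 10% in old vehicle, -0.0533 ± 0.0605 in old SAHA and -0.0183 ± 0.0575 in young vehicle. An exact test gave p = 0.00433 (924 splits, adjusted p = 0.00755) for SAHA and p = 0.00566 (3003 splits, adjusted p = 0.00755) for age. With that trend removed from each library, 23 genes passed for SAHA, 22 of the 913 among them, and 2373 were below 0.05 unadjusted. The median absolute fold change of the 913 genes went from 0.26 to 0.14 and their median standard error from 0.0625 to 0.0540, so in the median calls ended with smaller fold changes and not with larger errors. Of the 913, 879 kept their sign. Of the genes named here, Hbb-bt (1.68, adjusted p = 0.0113), Hbb-bs (1.42, adjusted p = 0.0113), Plin4 (1.27, adjusted p = 0.0134), Sult1a1 (0.92, adjusted p = 0.0464), Trp53inp1 (0.34, adjusted p = 0.0145) and Ccdc117 (0.33, adjusted p = 0.0217) passed and 28 did not. Those 28 included Hspa5 (0.24, adjusted p = 0.0524), Dnajc3 (0.26, adjusted p = 0.123) and Grin1 (-0.15, adjusted p = 0.261), while the chaperone list still passed (2.50e-09). For age, 547 genes passed after removal, 468 of the 891 among them. Of the genes named Hdac2 (-0.11, adjusted p = 0.0573), H2-DMa (0.31, adjusted p = 0.0744), Hspa8 (-0.11, adjusted p = 0.0977), Srebf2 (0.13, adjusted p = 0.0907), Sparc (0.20, adjusted p = 0.0821) and Rpusd1 (0.11, adjusted p = 0.112) did not pass.

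**Figure D2:**
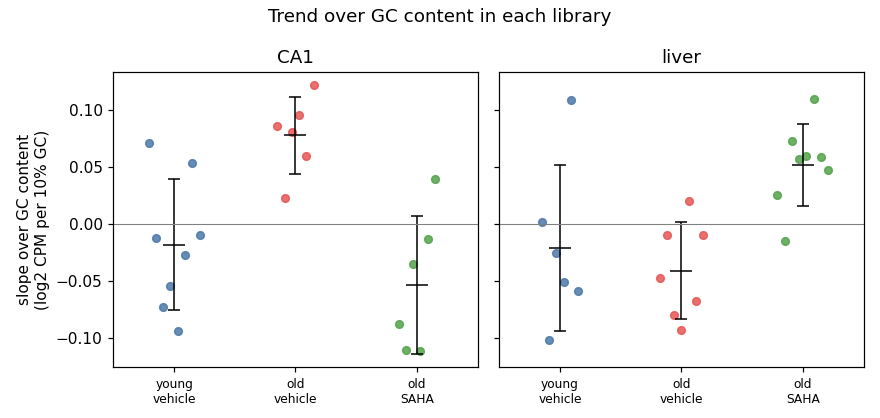
Change of log2 counts with GC content in each library of CA1 and liver. Points are libraries and black marks are mean ± SD.

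Of the lists, endoplasmic reticulum chaperones (7 of 17, 12, 0.12, 5.49e-08) and red blood cell markers (3 of 5, 5, 1.37, 1.69e-06) rose with SAHA in CA1, and cholesterol synthesis (1 of 18, 1, -0.13, 0.0126) fell. None passed under the stricter test (adjusted p = 0.265 to 0.834 with an estimated correlation). Neuronal lists gave immediate early genes (0.0502), synapse (0.120), CA1 pyramidal markers (0.319), CA3 and CA2 markers (0.851), dentate granule and newborn neuron markers (0.742), interneuron markers (0.464). Glial, vascular and choroid lists gave microglia markers (0.319), astrocyte markers (0.120), oligodendrocyte markers (0.596), oligodendrocyte precursor markers (0.557), brain endothelial and mural markers (0.0760), choroid plexus markers (0.0770). Immune lists gave MHC class I presentation (0.453), MHC class II presentation (0.549), interferon response (0.557), complement (0.596). The others gave histone deacetylases (0.296), histone acetyltransferases (0.675), cytosolic heat shock (0.296), oxidative phosphorylation (0.547), collagens and extracellular matrix (0.596), cell cycle (0.557), p53 targets and senescence (0.292), circadian clock (0.557). Test, median and mean differed in sign for CA3 and CA2 and for dentate markers. Genes that did not pass were Tap2 (-0.27 ± 0.14, 0.247), H2-Eb1 (2.16 ± 0.74, 0.0835), Mx1 (-1.46 ± 0.55, 0.117), Hsph1 (0.14 ± 0.05, 0.117) and Col3a1 (1.62 ± 0.65, 0.139). Further ones were Plk1 (-0.33 ± 0.19, 0.324), Lck (-0.19 ± 0.14, 0.453), Ighm (1.20 ± 0.51, 0.158), Npas4 (-0.70 ± 0.24, 0.0797), Trem2 (-0.29 ± 0.12, 0.136) and Opalin (-0.40 ± 0.19, 0.207). The last were Slco1a4 (0.26 ± 0.08, 0.0774), Mpped1 (-0.13 ± 0.05, 0.147), Coch (1.19 ± 0.44, 0.105), Igfbpl1 (-1.99 ± 0.70, 0.0925) and Slc32a1 (-0.21 ± 0.08, 0.115).

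Immune and glial genes differed between old CA1 given SAHA and young CA1. C4b (2.46 ± 0.20, 1.82e-07) stood at 142 ± 58.1 CPM in old SAHA and 25.7 ± 3.72 CPM in young vehicle. Gfap (0.79 ± 0.11, 1.93e-04) stood at 605 ± 122 and 349 ± 30.2 CPM, and Gpr17 (-0.85 ± 0.09, 6.15e-06) at 37.5 ± 4.78 and 67.7 ± 7.80 CPM. Lists higher than in young CA1 were MHC class I presentation (5 of 11, 10, 0.74, 2.60e-08), MHC class II presentation (4 of 7, 5, 2.52, 0.00305), interferon response (2 of 15, 10, 0.91, 8.34e-07) and complement (5 of 11, 10, 0.95, 1.70e-09). Higher too were endoplasmic reticulum chaperones (0 of 17, 2, 0.02, 0.0263), red blood cell markers (3 of 5, 5, 1.16, 9.17e-07) and microglia markers (9 of 12, 12, 0.41, 3.22e-16). The same held for astrocyte markers (4 of 11, 7, 0.20, 2.22e-07), brain endothelial and mural markers (0 of 12, 1, 0.16, 0.0205) and choroid plexus markers (4 of 6, 6, 3.79, 0.0205). Lists that were lower were histone deacetylases (0 of 11, 0, -0.09, 0.0136), cholesterol synthesis (0 of 18, 0, -0.08, 0.00774) and cell cycle (1 of 8, 4, -0.51, 0.00196). Lower too were circadian clock (0 of 14, 1, -0.06, 0.0263), immediate early genes (5 of 16, 10, -0.35, 9.17e-07) and oligodendrocyte precursor markers (2 of 6, 2, -0.07, 0.00557). None passed under the stricter test (adjusted p = 0.0900 to 0.611 with an estimated correlation). The others gave histone acetyltransferases (0.792), cytosolic heat shock (0.925), oxidative phosphorylation (0.569), collagens and extracellular matrix (0.476), p53 targets and senescence (0.476) and synapse (0.380). The rest gave oligodendrocyte markers (0.0609), CA1 pyramidal markers (0.825), CA3 and CA2 markers (0.447), dentate granule and newborn neuron markers (0.792) and interneuron markers (0.304). Histone acetyltransferase and dentate lists differed in sign between test, median and mean. Without old SAHA library 5, which held most of the choroid plexus transcripts, choroid plexus (0.215), endothelial and mural (0.476) and chaperone (0.215) lists no longer passed, and 7 lists were higher. In all, 587 of 16554 genes differed from young (393 higher, 194 lower, 105 by more than 2-fold, median absolute log2 fold change 0.49), 334 without old SAHA library 5, 61 with a red blood cell score in the model and 243 with a choroid plexus score.

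Age and SAHA fold changes ran against each other in CA1. Trp53inp1 (age -0.34 ± 0.05, 4.17e-04, SAHA 0.42 ± 0.05, 0.00207) fell with age and rose with SAHA, to 27.3 ± 1.14 CPM against 25.9 ± 1.97 CPM in young vehicle. So did Ccdc117 (age -0.37 ± 0.06, 8.96e-04, SAHA 0.37 ± 0.06, 0.00566), of unknown function, with 25.0 ± 2.14, 19.4 ± 0.83 and 25.0 ± 1.79 CPM in young vehicle, old vehicle and old SAHA. Ccar1 (age -0.24 ± 0.04, 0.00181, SAHA 0.25 ± 0.04, 0.00637), a regulator of cell division and apoptosis, did so with 72.6 ± 4.48, 61.4 ± 2.56 and 73.1 ± 3.25 CPM. 2610008E11Rik (age -0.22 ± 0.04, 0.00461, SAHA 0.24 ± 0.04, 0.00738), a zinc finger gene, moved likewise. Rpusd1 (age 0.21 ± 0.04, 0.00283, SAHA -0.25 ± 0.04, 0.00566), a pseudouridine synthase gene, rose with age and fell with SAHA. In total 209 genes passed in opposite directions, 128 higher with age and lower with SAHA (19.7 if independent) and 81 the reverse (6.48), and 0 passed in the same direction (9.61 and 13.3). The old vehicle libraries enter both differences, which by itself makes fold changes run against each other: in 20 simulated data sets with no group differences their covariance had a mean of -0.0133, and -0.0259 was observed. The observed correlation was weaker than the simulated mean (-0.386 against -0.520), and the Spearman correlation lay near it (-0.490 against -0.475). With the old vehicle libraries split so that each fold change had its own, the covariance had a median of -0.0164 and was below 0 in 20 of 20 fits. A median of 1 gene (0 to 8) passed in opposite directions. Among genes that passed for age the slope of the SAHA on the age fold change was -0.207, but a median of -0.0148 (-0.110 to 0.0653, below 0 in 13 of 20) in the split fits. There a median of 84.1% (71.2% to 94.3%) of genes lower with age had higher SAHA values, and 60.0% (34.2% to 80.8%) of genes higher with age had lower ones. The number was 60, 73 and 55 without old vehicle libraries 4, 5 and 6, and 9 with the GC trend removed, where 23 genes passed for SAHA and the split fits had a median covariance of -0.0119. Of the genes that passed for age 83.4% had the opposite sign for SAHA, 90.9% among the same number of top genes of the simulations and 66.8% in the split fits. The genes are not independent replicates.

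**Figure D3:**
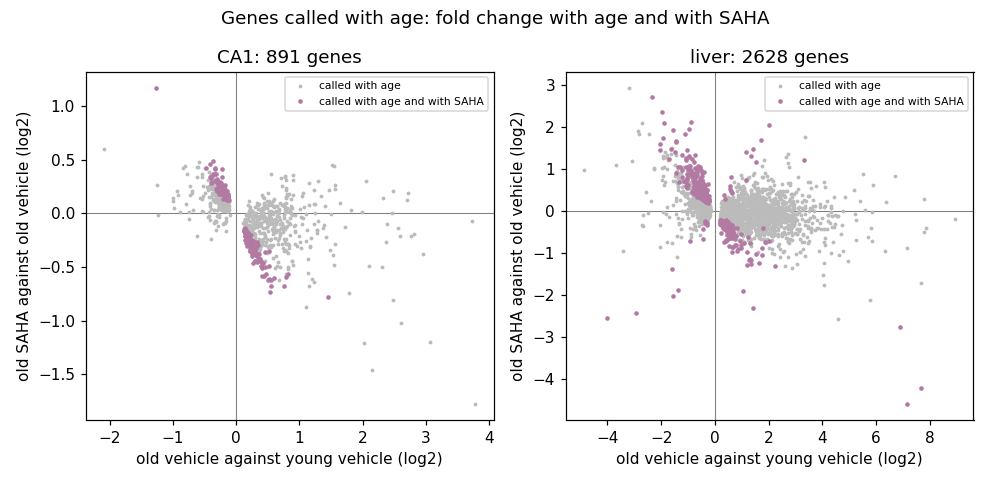
Log2 fold change for SAHA against log2 fold change for age, in CA1 and in liver. Each point is 1 gene.

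Relative use of exon parts differed in CA1, with the gene's adjusted p, the part of smallest p and its log2 change relative to the gene in brackets. With age it changed most in Ddx5 (4.99e-22, part 35 by 1.30), an RNA helicase gene merged with the small RNA genes Mir3064 and Gm25994 (chr11:106780355-106789185). Next were Nptn (1.14e-20, part 7 by 0.80), a synaptic adhesion gene, and Dnm1 (6.06e-19, part 16 by 0.74), dynamin 1 of synaptic vesicle endocytosis. Rbm3 (2.85e-12, part 2 by -0.87), a cold-induced RNA-binding protein gene, followed, as did Smarcc2 (5.91e-12, part 28 by 0.43), a chromatin remodelling subunit. With SAHA it changed most in Lars2 (4.25e-61, part 12 by -1.81), Sf1 (7.07e-20, part 34 by -0.53), splicing factor 1, and Nisch (3.40e-18, part 15 by -0.40), the imidazoline-binding nischarin. Next were Chd3 (3.40e-18, part 4 by -0.51), a chromatin remodeller, and Wdr13 (5.87e-17, part 12 by -0.46). Of 12421 genes tested with diffSpliceDGE, 1262 passed for age and 1673 for SAHA (973 without old SAHA library 5). Of these, 77 and 252 also passed the gene test (64.9 and 103 if independent). Both tests passed 837 genes (170 if independent) but share the old vehicle libraries, so their calls are not separate. The GC trend was neither removed nor tested for exon parts. The end part of Lars2 held 82.1% of its reads in old SAHA, 65.0% in old vehicle and 69.4% in young vehicle, while its other parts held 17.7 ± 0.487, 17.8 ± 0.612 and 17.6 ± 1.02 CPM. That end part stood at 263 ± 376, 34.6 ± 10.1 and 55.4 ± 50.4 CPM, so the relative fall of part 12 with SAHA came from the end part. Exon part counts of 8 young libraries matched the gene counts of another young number best, which leaves the groups as they are, and those of old SAHA library 5 matched none.

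In old liver, genes of plasma cells, T cells and inflammation rose. Jchain (3.97 ± 0.38, 1.55e-06), the joining chain of secreted antibodies (ENSMUSG00000067149, chr5:88519809-88527891), rose from 1.04 ± 0.546 CPM in young vehicle (n = 6) to 16.3 ± 3.05 CPM in old vehicle (n = 7). The light chain gene Igkc (4.59 ± 0.41, 8.42e-07) and the T cell genes Ccl5 (3.69 ± 0.86, 0.00721) and Cd3g (2.93 ± 0.72, 0.00911) rose with it. Myeloid genes rose, Clec4n (3.26 ± 0.86, 0.0130), Clec12a (3.03 ± 0.74, 0.00925), Itgax (2.62 ± 0.61, 0.00718), Lyz2 (2.51 ± 0.49, 0.00233), Wfdc17 (2.95 ± 0.76, 0.0115), C1qa (2.11 ± 0.56, 0.0135) and C1qc (2.03 ± 0.54, 0.0143). So did genes of antigen presentation, Nlrc5 (0.95 ± 0.16, 9.86e-04), Psmb9 (1.19 ± 0.23, 0.00191), H2-DMb1 (2.28 ± 0.60, 0.0133) and Ciita (1.86 ± 0.51, 0.0158). Of the interferon response Usp18 (1.78 ± 0.33, 0.00167) and Ifi27 (1.34 ± 0.22, 6.56e-04) rose. The acute phase genes Lcn2 (4.08 ± 0.89, 0.00476) and Saa3 (1.38 ± 0.33, 0.00802), a member of the Saa family, were higher. Higher too were Ntrk2 (3.58 ± 0.51, 2.44e-04), a neurotrophin receptor gene, the metallothionein gene Mt2 (3.45 ± 0.98, 0.0185), and the stem cell antigen Ly6a (3.16 ± 0.77, 0.00911). The mitotic genes Aurkb (3.49 ± 0.84, 0.00821) and Cdc20 (2.72 ± 0.67, 0.00948) rose. Cholesterol synthesis genes rose, Hmgcs1 (1.1 ± 0.19, 0.00124) and Msmo1 (0.79 ± 0.17, 0.00396). So did the drug metabolism genes Cyp2b9 (3.90 ± 0.93, 0.00837) and Nqo1 (0.91 ± 0.25, 0.0164), the early gene Egr1 (2.88 ± 0.58, 0.00288), the deacetylase Hdac11 (0.40 ± 0.12, 0.0250) and the p53 target Ccng1 (0.34 ± 0.12, 0.0468).

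Chaperone genes fell in old liver, as did some clock and hepatocyte genes. Hspa5 (-0.80 ± 0.12, 5.39e-04) fell from 906 ± 128 to 522 ± 40.2 CPM and Manf (-1.06 ± 0.16, 3.03e-04), a secreted endoplasmic reticulum stress protein, fell with it. So did the heat shock genes Hspa1a (-3.10 ± 0.50, 6.40e-04), Hspa1b (-1.98 ± 0.37, 0.00176) and Hsph1 (-1.41 ± 0.23, 6.56e-04). The clock genes Arntl (-1.95 ± 0.47, 0.00847), which encodes BMAL1 (ENSMUSG00000055116, chr7:113207465-113314126), Clock (-0.99 ± 0.15, 4.11e-04) and Cry1 (-1.03 ± 0.18, 9.57e-04) fell, Arntl from 6.64 ± 4.10 to 1.72 ± 0.734 CPM. Of the 13 clock genes tested 4 passed as lower and 2 as higher with age. Male-typical genes fell, Mup17 (-4.02 ± 0.90, 0.00581), from 539 ± 383 to 33.3 ± 51.8 CPM, Elovl3 (-1.92 ± 0.49, 0.0113), Cyp4a12b (-1.19 ± 0.32, 0.0152) and Ugt2b38 (-2.06 ± 0.61, 0.0225). Hepatocyte genes fell, Cyp3a11 (-0.72 ± 0.17, 0.00743), Hnf4a (-0.39 ± 0.12, 0.0289), Tat (-0.84 ± 0.20, 0.00802) and G6pc (-1.37 ± 0.34, 0.0103). Falls came also from lipid genes, Thrsp (-1.17 ± 0.35, 0.0253), Hadha (-0.39 ± 0.11, 0.0152) and Acot1 (-1.44 ± 0.41, 0.0180), and from Atp5g1 (-0.60 ± 0.13, 0.00592) and Ndufv1 (-0.40 ± 0.10, 0.0117) of the respiratory chain. Lower too were the channel gene Clic3 (-2.33 ± 0.47, 0.00319), Lars2 (-1.81 ± 0.51, 0.0183), the repressor Bcl6 (-1.77 ± 0.49, 0.0166) and Gstp1 (-1.24 ± 0.26, 0.00415). Krt19 (-1.22 ± 0.26, 0.00430), Dusp1 (-1.07 ± 0.27, 0.0110) and Kat8 (-0.38 ± 0.11, 0.0232) fell too. Mup, Ugt2b, Cyp2b, Cyp4a12 and Hspa1 genes have near-identical copies, so the copy is uncertain.

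Of 14068 genes tested in liver, 2628 passed for age (1528 higher, 1100 lower), 1045 of them by more than 2-fold, with a median absolute log2 fold change of 0.71. 53 of the 63 passing genes named here passed whichever 1 library was left out. The others reached an adjusted p of 0.0541 (Acot1), 0.0506 (C1qc), 0.113 (Ccng1), 0.0582 (Hdac11), 0.0761 (Hnf4a), 0.0634 (Kat8), 0.0771 (Lars2), 0.148 (Mt2), 0.0602 (Thrsp) and 0.0637 (Ugt2b38) without 1 library. Such losses, counted in brackets, came without old vehicle libraries 2 (2), 3 (1), 4 (1), 5 (4), 7 (2) and young libraries 1 (1), 2 (2), 3 (1), 4 (5), 5 (4), 6 (3). Old vehicle library 5 stood far above the others for most of the myeloid, T cell, antigen presentation and interferon genes named, such as Clec12a (93.7 CPM, next 20.4), C1qa (394 CPM, next 102) and Ccl5 (37.2 CPM, next 12.2). Without it 1671 genes passed, and the fold changes were 1.88 for Clec12a, 1.19 for C1qa and 2.71 for Ccl5. Mt2 was at 1.41 without old vehicle library 7. With an immune cell score in the model 372 genes passed and C1qa (-0.74), Clec4n (-0.90) and H2-DMb1 (-0.46) had the opposite sign. With a clock gene score in the model 121 passed, and Arntl was at 0.54.

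Lists that rose with age in liver were B and plasma cell markers (8 of 8, 8, 2.0, 4.14e-07), MHC class I presentation (10 of 11, 10, 0.72, 4.42e-09) and interferon response (11 of 15, 13, 1.43, 3.45e-07). Cholesterol synthesis (6 of 18, 7, 0.39, 1.26e-04) and T and NK cell markers (9 of 11, 11, 2.88, 1.89e-04) rose as well. Kupffer cell and macrophage markers (9 of 12, 9, 1.90, 0.00158), MHC class II presentation (7 of 7, 7, 1.91, 0.00164), cell cycle (8 of 11, 9, 1.96, 0.0124) and acute phase (4 of 13, 4, 0.37, 0.0171) rose too. Those that fell were endoplasmic reticulum chaperones (15 of 17, 16, -0.56, 8.61e-13), cytosolic heat shock (9 of 10, 10, -0.73, 4.42e-09), oxidative phosphorylation (11 of 16, 16, -0.34, 1.57e-07) and male-biased liver genes (2 of 8, 3, -0.63, 0.00899). Hepatocyte markers (1 of 10, 1, -0.24, 0.0220), gluconeogenesis (2 of 6, 2, -0.26, 0.0332) and fatty acid oxidation and PPARA targets (3 of 14, 3, -0.21, 0.0392) also fell. Without old vehicle library 5 the rising lists still passed, and hepatocyte markers (0.0656) and fatty acid oxidation (0.0718) did not. None passed under the stricter test (adjusted p = 0.172 to 0.584 with an estimated correlation). Other metabolic lists gave fatty acid synthesis (0.0528), bile acid synthesis and transport (0.383), cytochrome P450 drug metabolism (0.652), conjugation and NRF2 targets (0.764), female-biased liver genes (0.559). The rest gave histone deacetylases (0.211), histone acetyltransferases (0.383), complement (0.211), collagens and extracellular matrix (0.644), p53 targets and senescence (0.894), circadian clock (0.941), red blood cell markers (0.383), immediate early genes (0.180), liver endothelial markers (0.751), cholangiocyte markers (0.0594). Clock and red blood cell lists differed in sign between test, median and mean. Genes that did not pass were Dcn (0.50 ± 0.19, 0.0641), Alas2 (-0.40 ± 0.22, 0.200), Fcgr2b (0.35 ± 0.16, 0.145) and Cyp8b1 (-0.76 ± 0.29, 0.0697).

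**Figure D4:**
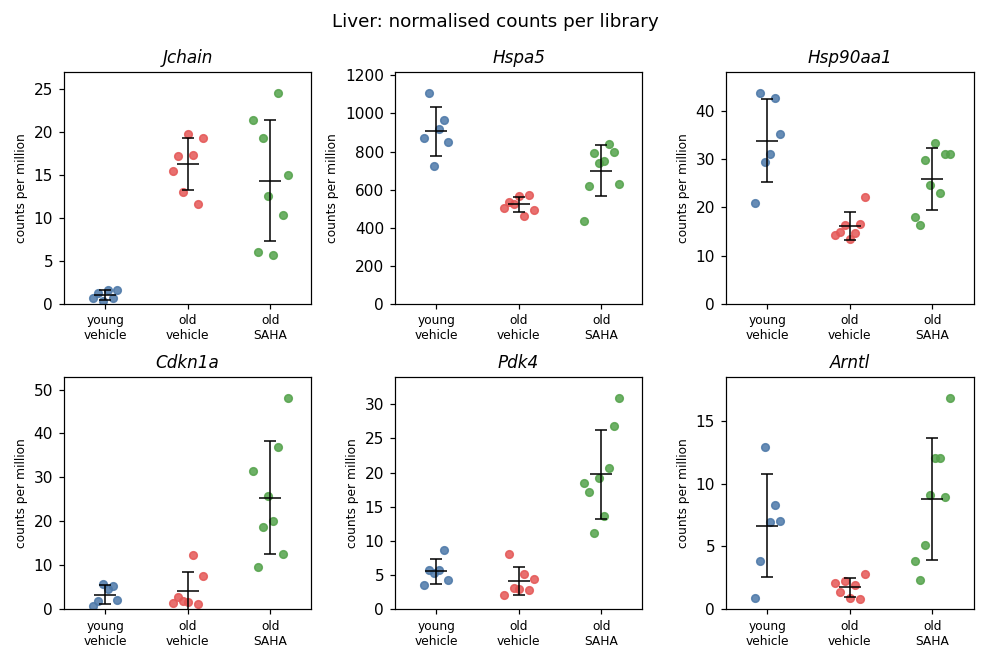
CPM of 6 genes in liver of young vehicle (n = 6), old vehicle (n = 7) and old SAHA (n = 8). Points are libraries and black marks are mean ± SD.

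With SAHA, old liver showed higher values of the cell cycle inhibitor p21, of a fasting-induced kinase and of chaperones. Cdkn1a (2.60 ± 0.51, 0.00290), which encodes p21 (ENSMUSG00000023067, chr17:29090976-29100727), rose from 4.10 ± 4.23 CPM in old vehicle (n = 7) to 25.4 ± 12.9 CPM in old SAHA (n = 8), with the p53 target Trp53inp1 (0.50 ± 0.14, 0.0296). Pdk4 (2.26 ± 0.27, 1.29e-04), which restrains pyruvate oxidation (ENSMUSG00000019577, chr6:5483351-5496309), rose from 4.08 ± 2.06 to 19.8 ± 6.50 CPM. Chaperone genes rose, Hyou1 (0.80 ± 0.18, 0.00742), Creld2 (0.90 ± 0.22, 0.0117), Hsp90aa1 (0.69 ± 0.17, 0.0116), from 16.1 ± 2.92 to 25.9 ± 6.40 CPM and Hspa8 (0.40 ± 0.12, 0.0400). The tubulin genes Tubb2a (2.12 ± 0.38, 0.00156) and Tuba8 (1.94 ± 0.41, 0.00515) rose as well. Conjugation and transport genes were higher, Gsta2 (1.21 ± 0.20, 8.31e-04), Gsta4 (0.52 ± 0.10, 0.00346), Cyp3a11 (0.68 ± 0.16, 0.00967) and the bile acid transporters Slc51b (2.0 ± 0.38, 0.00228) and Abcb11 (0.40 ± 0.11, 0.0249) (Gsta2 has near-identical copies). So were the channel gene Clic3 (2.70 ± 0.46, 0.00105), the endosome gene Rab11fip4 (2.12 ± 0.26, 1.29e-04), the calcium-binding Cib3 (1.95 ± 0.32, 8.41e-04) and the keratin Krt19 (0.96 ± 0.24, 0.0155). The matrix gene Lum (0.81 ± 0.26, 0.0450), complement C3 (0.52 ± 0.13, 0.0158) and the deacetylase Hdac5 (0.45 ± 0.12, 0.0210) rose too.

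Clock genes moved with SAHA in liver, Arntl (2.35 ± 0.45, 0.00264) and Clock (0.96 ± 0.14, 4.25e-04) upward and Dbp (-2.33 ± 0.40, 0.00109) and Nr1d1 (-1.76 ± 0.28, 6.56e-04) downward. Some male-typical genes fell, Hsd3b5 (-2.79 ± 0.87, 0.0427), Mup17 (-2.56 ± 0.83, 0.0497), Mup21 (-1.88 ± 0.37, 0.00280) and Cyp7b1 (-1.04 ± 0.31, 0.0334), whose Mup copies are near-identical. The list of male-biased liver genes did not pass for SAHA, and 3 of 19 Mup genes passed as lower. Further falls were of the G protein regulator Rgs16 (-2.27 ± 0.62, 0.0227), the antisense transcript Hectd2os (-1.89 ± 0.40, 0.00488), the forkhead gene Foxq1 (-1.89 ± 0.54, 0.0286), and the malic enzyme Me1 (-0.85 ± 0.19, 0.00648). Nsdhl (-0.50 ± 0.14, 0.0233) of sterol synthesis, complement C1ra (-0.31 ± 0.08, 0.0160) and the chromatin enzymes Hdac11 (-0.71 ± 0.11, 6.39e-04) and Kat2b (-0.45 ± 0.09, 0.00393) fell as well.

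Of 14068 genes, 1508 passed for SAHA in liver (745 higher, 763 lower), 213 of them by more than 2-fold, with a median absolute log2 fold change of 0.48. 31 of the 41 passing genes named here passed whichever 1 library was left out. The others reached an adjusted p of 0.0524 (Abcb11), 0.0777 (Cyp7b1), 0.0727 (Foxq1), 0.0833 (Hsd3b5), 0.0830 (Hspa8), 0.102 (Lum), 0.238 (Mup17), 0.0642 (Nsdhl), 0.0636 (Rgs16) and 0.0661 (Trp53inp1) without 1 library. Such losses, counted in brackets, came without old SAHA libraries 1 (4), 2 (1), 3 (4), 4 (6), 5 (1), 6 (3), 7 (2), 8 (7) and old vehicle libraries 1 (7), 2 (5), 3 (8), 4 (6), 5 (1), 6 (7), 7 (1). Without old vehicle library 3 the number of passing genes was 1005 and without old SAHA library 8 it was 975. It was 451 without libraries in which over 10% of the exon table reads fell in no part. Mup17 was at -1.41 without old vehicle library 4. With a score of the 13 clock genes in the model, edgeR passed 0 genes (814 below 0.05 unadjusted). The median absolute fold change of the 1508 genes went from 0.48 to 0.24 and their median standard error from 0.118 to 0.213. The score itself differed between old SAHA (-0.780 ± 0.697) and old vehicle (1.16 ± 0.275, exact test, p = 0.000311). Arntl (-0.85), Dbp (0.11), Rgs16 (0.23), Hdac5 (-0.20), Hsp90aa1 (-0.22) and Hspa8 (-0.12) then had the opposite sign.

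Lists that rose with SAHA in liver were conjugation and NRF2 targets (3 of 15, 5, 0.35, 0.0151), collagens and extracellular matrix (1 of 11, 3, 0.50, 0.0151) and p53 targets and senescence (2 of 8, 3, 0.37, 0.0167). Cytosolic heat shock (2 of 10, 6, 0.47, 0.0251), endoplasmic reticulum chaperones (5 of 17, 6, 0.18, 0.0300) and cholangiocyte markers (1 of 5, 1, 0.58, 0.0338) rose as well. Without old vehicle library 5 the last 3 did not pass (0.0892, 0.132 and 0.0712). None passed under the stricter test (adjusted p = 0.987 with an estimated correlation for each of them). The circadian clock list, with 3 genes higher and 6 lower of 13, gave an adjusted p of 0.0843. Immune lists gave MHC class I presentation (0.596), MHC class II presentation (0.784), interferon response (0.449), complement (0.784), T and NK cell markers (0.966), B and plasma cell markers (0.784), Kupffer cell and macrophage markers (0.637), acute phase (0.637). Metabolic lists gave oxidative phosphorylation (0.125), cholesterol synthesis (0.669), cytochrome P450 drug metabolism (0.805), fatty acid synthesis (0.875), fatty acid oxidation and PPARA targets (0.531), bile acid synthesis and transport (0.637), gluconeogenesis (0.998), male-biased liver genes (0.125), female-biased liver genes (0.214). The rest gave histone deacetylases (0.784), histone acetyltransferases (0.443), cell cycle (0.998), red blood cell markers (0.449), immediate early genes (0.669), hepatocyte markers (0.783), liver endothelial markers (0.637). Cell cycle, immediate early, acute phase, fatty acid oxidation and gluconeogenesis lists differed in sign between test, median and mean. Genes that did not pass were B2m (-0.26 ± 0.11, 0.121), Ciita (0.31 ± 0.43, 0.693), Irf9 (-0.33 ± 0.12, 0.0820), Uqcrc2 (-0.22 ± 0.10, 0.180) and Birc5 (-0.39 ± 0.37, 0.539). Immune and blood genes were Cd4 (-0.83 ± 0.68, 0.467), Ms4a1 (0.47 ± 0.52, 0.609), Alas2 (-0.33 ± 0.20, 0.302), Marco (2.13 ± 0.88, 0.119) and Saa2 (0.80 ± 0.46, 0.274). Others were Junb (-0.70 ± 0.26, 0.0812), Trf (0.32 ± 0.14, 0.130), Stab1 (0.29 ± 0.14, 0.182) and G6pc (0.58 ± 0.32, 0.251).

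Old liver given SAHA was above young liver in plasma cell genes and below it in male-biased genes. Jchain (3.8 ± 0.37, 3.58e-06) stood at 14.4 ± 6.99 against 1.04 ± 0.546 CPM. Mup17 (-6.59 ± 0.96, 1.77e-04) stood at 5.72 ± 5.77 against 539 ± 383 CPM and Hspa5 (-0.37 ± 0.12, 0.0219) at 700 ± 132 against 906 ± 128 CPM. Lists higher than in young liver were MHC class I presentation (10 of 11, 10, 0.66, 1.84e-05), MHC class II presentation (7 of 7, 7, 2.03, 0.00326), interferon response (12 of 15, 13, 1.22, 3.04e-04) and cholesterol synthesis (9 of 18, 10, 0.40, 3.04e-04). More of them were collagens and extracellular matrix (4 of 11, 4, 0.74, 0.00831), cell cycle (6 of 11, 7, 1.49, 0.0275) and p53 targets and senescence (3 of 8, 4, 0.30, 0.0196). Immune and other lists were T and NK cell markers (9 of 11, 10, 2.62, 0.00199), B and plasma cell markers (7 of 8, 8, 2.20, 3.30e-05) and Kupffer cell and macrophage markers (10 of 12, 11, 2.20, 0.00150). The last higher ones were acute phase (6 of 13, 6, 0.52, 0.0104) and conjugation and NRF2 targets (9 of 15, 10, 0.42, 0.0127). Lower lists were endoplasmic reticulum chaperones (11 of 17, 12, -0.38, 1.57e-05), cytosolic heat shock (7 of 10, 8, -0.40, 6.15e-04), oxidative phosphorylation (16 of 16, 16, -0.45, 3.82e-08) and circadian clock (4 of 13, 4, -0.28, 0.0151). Metabolic ones that were lower were male-biased liver genes (6 of 8, 7, -1.45, 3.04e-04), fatty acid oxidation and PPARA targets (6 of 14, 6, -0.30, 0.0151) and gluconeogenesis (2 of 6, 2, -0.36, 0.0471). None passed under the stricter test (adjusted p = 0.425 to 0.582 with an estimated correlation). The others gave histone deacetylases (0.501), histone acetyltransferases (0.0599), complement (0.492), red blood cell markers (0.879), immediate early genes (0.0942) and hepatocyte markers (0.110). The rest gave liver endothelial markers (0.355), cholangiocyte markers (0.879), cytochrome P450 drug metabolism (0.501), female-biased liver genes (0.0942), fatty acid synthesis (0.143) and bile acid synthesis and transport (0.951). Complement and bile acid lists differed in sign between test, median and mean. Of 14068 genes, 4696 passed (2494 higher, 2202 lower, 1473 by more than 2-fold, median absolute log2 fold change 0.57). The number was 375 with a surrogate variable in the model, 119 with an immune cell score and 739 without libraries in which over 10% of the exon table reads fell in no part.

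Some genes changed in opposite directions with age and SAHA in liver. Gldc (age -1.08 ± 0.14, 5.60e-05, SAHA 1.05 ± 0.13, 1.29e-04), of glycine cleavage, stood at 197 ± 29.8, 93.4 ± 18.5 and 193 ± 36.3 CPM in young vehicle, old vehicle and old SAHA. Clock (age -0.99 ± 0.15, 4.11e-04, SAHA 0.96 ± 0.14, 4.25e-04) did likewise. Mal2 (age -0.77 ± 0.11, 3.44e-04, SAHA 0.67 ± 0.11, 8.31e-04), a transcytosis gene, and Plin5 (age -1.04 ± 0.13, 5.60e-05, SAHA 0.75 ± 0.12, 8.58e-04), a lipid droplet coat gene, also fell with age and rose with SAHA. Gnat1 (age 1.07 ± 0.13, 4.84e-05, SAHA -0.78 ± 0.12, 6.39e-04), a transducin subunit, did the reverse. In total 336 genes passed in opposite directions, 125 higher with age and lower with SAHA and 211 the reverse (82.9 and 58.3 if independent). A further 28 passed in the same direction, 15 higher and 13 lower (80.9 and 59.7). The covariance of the fold changes was -0.0544, and -0.0339 in the mean of simulated data sets with no group differences. The correlation was weaker than simulated (-0.186 against -0.494), as was the Spearman correlation (-0.181 against -0.453). With the old vehicle libraries split it had a median of -0.0165 (range -0.101 to 0.273) and was below 0 in 39 of 70 fits. A median of 52 genes passed in opposite directions. The slope among genes that passed for age was -0.121, and a median of -0.00604 (-0.199 to 0.307) in the split fits. Of the genes that passed for age 68.5% had the opposite sign for SAHA, 83.6% among as many top genes of the simulations and 61.0% in the split fits. These genes too are not independent replicates. With the clock gene score in the model 0 genes passed in opposite directions, since 0 passed for SAHA with edgeR (814 below 0.05 unadjusted).

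Few liver genes passed the test of exon part use. With age these were first Lars2 (6.43e-38, part 16 by 1.38) and the merged genes Cdhr4, Ip6k1, Uba7, Gm20661 and Gm20662 (2.40e-28, part 36 by 0.71). Next were the merged genes Arhgap4, Naa10 and L1cam (6.97e-21, part 64 by 1.33), the merged genes Eif4ebp3 and Ankhd1 (7.82e-19, part 52 by 0.44) and Prkd3 (3.66e-16, part 8 by -0.57), a protein kinase D gene. With SAHA they were Lars2 (4.43e-28, part 20 by -1.03) and Psen2 (7.18e-17, part 21 by -0.56), presenilin 2. Next were the merged glutathione transferase genes Gstm6, Gm12494 and Gstm3 (2.06e-14, part 5 by -0.76), whose copies are near-identical, Pnkd (2.06e-14, part 9 by -0.77) and the merged genes Plec and Parp10 (7.02e-14, part 5 by 0.49). Of 10372 genes, 61 passed for age and 54 for SAHA, and 13 passed for both (0.318 if independent), where the old vehicle libraries are shared. The end part of Lars2 held 98.2% of its reads in old vehicle, 98.8% in old SAHA and 99.2% in young vehicle. That part stood at 674 ± 344, 1697 ± 1265 and 2308 ± 1972 CPM, and the other parts at 10.3 ± 1.02, 10.5 ± 1.56 and 11.2 ± 0.929 CPM, so the fall of Lars2 with age came from its end part.

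The effects of age and of SAHA differed between the 2 tissues for many genes, tested as the liver effect minus the CA1 effect. For age these were C4b (-2.22 ± 0.26, 4.58e-07, with 2.46 in CA1 and 0.25 in liver) and Prex1 (1.70 ± 0.15, 1.60e-09, with 0.07 in CA1 and 1.78 in liver), a Rac exchange factor. Next were Cdh19 (6.01 ± 0.56, 3.13e-09, with -0.12 in CA1 and 5.85 in liver), a cadherin of glial cells, Zfp788 (1.07 ± 0.11, 2.13e-08, with -0.18 in CA1 and 0.90 in liver), a zinc finger gene, and Wasf1 (-1.53 ± 0.17, 2.07e-07, with 0.18 in CA1 and -1.34 in liver), an actin regulator. For SAHA they were Kifc3 (1.42 ± 0.16, 6.97e-07, with -0.33 in CA1 and 1.05 in liver), a kinesin gene, and Clint1 (0.59 ± 0.07, 4.51e-06, with 0.05 in CA1 and 0.59 in liver), a clathrin adaptor. They were followed by Rab11fip4 (2.16 ± 0.27, 6.05e-06, with 0.01 in CA1 and 2.12 in liver), a recycling endosome gene, Lad1 (2.07 ± 0.27, 8.78e-06, with -0.21 in CA1 and 1.82 in liver), a basement membrane anchoring gene, and Gtf3c1 (0.55 ± 0.08, 2.74e-05, with -0.14 in CA1 and 0.36 in liver), a subunit of TFIIIC. Of 17826 genes tested, 1908 differed for age (977 higher in liver, 931 lower) and 1416 for SAHA (938 and 478). Of 12621 genes tested in each tissue, 243 passed for age in both, 214 in the same direction (175 higher and 39 lower, 43.6 and 26.0 if independent) and 29 in opposite directions (67.4). For SAHA 98 passed in both, 48 in the same direction (19 higher and 29 lower, 15.1 and 27.7 if independent) and 50 in opposite directions (42.7).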

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

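The tests of the GC trend on the SAHA genes of CA1, of the shared old vehicle libraries, of time of day, of choroid plexus tissue and of mismatched tables were chosen only after the results were seen. The GC trend and the clock score were steps chosen after seeing the data, but how the opposite changes and an action of SAHA on the clock would come out under them had not been seen. All tests by other splits of the libraries were written before.

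In CA1, age and SAHA fold changes ran against each other and SAHA genes differed in GC content. Removing the GC trend left 22 of the 913 SAHA genes passing, so a technical trend between the libraries may account for most of those calls, although a treatment that acts on GC-rich genes would look alike and the test cannot separate the 2. Without the trend the split-library covariance was -0.0119 (-0.0164 with it) and below 0 in 20 of 20 fits, so its removal did not take the covariance away. Other measures were less uniform. The Spearman correlation was below 0 in 19 of 20 fits, and the slope among genes that passed for age in 13 of 20. A median of 0 genes passed in opposite directions. The fits reuse the same libraries and a spline may leave part of a trend, so they cannot exclude the trend as the cause. A part of the opposition went with the trend, since the split Spearman correlation went from -0.271 to -0.140 and opposite signs among genes that passed for age from 66.8% to 58.3%. Noise in the shared old vehicle libraries would not by itself give a covariance below 0 in the split fits, where it was below 0 in 20 of 20. Those fits came from 10 splits of the same libraries and are not independent. A shift common to all old vehicle libraries would stay in both parts of a split, so the fits cannot exclude it.

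In liver, the clock genes Arntl, Clock and Dbp passed in opposite directions for age and SAHA, which share the old vehicle libraries. Across 13 clock genes, which are not independent replicates, the axis along which libraries of the same group differed ran with the SAHA fold changes (r = 0.979), so collection at different times of day could give the same pattern. With the clock score in the model 0 of the 9 passing clock genes still passed, which leaves an action of SAHA on the clock neither shown nor excluded. Collection times are not given in the sources used here.

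In CA1, old SAHA library 5 stood apart with choroid plexus transcripts. All 6 choroid plexus markers were high in it (Ttr 7120 CPM, at most 29.1 elsewhere; Kl 152 and 24.7; Clic6 79.2 and 1.74; F5 81.7 and 1.72; Aqp1 28.3 and 0.941; Prlr 33 and 11.4), which is consistent with choroid plexus in the dissected piece. Its gene and exon part counts correlated at only r = 0.0312, where 11 CA1 libraries matched their own number at 0.958 or more, so the tables of that number likely hold different libraries. The 2 explanations do not exclude each other.

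Other splits of the libraries asked whether chance can be excluded, counting the splits, the real one included, that gave as many calls. In CA1, 1 of 80 did for age (891 genes, at most 4 otherwise), 1 of 80 for SAHA (913, at most 391), 1 of 80 for old SAHA against young (587, at most 155) and 1 of 80 for opposite changes (209, at most 16). In liver these were 1 of 80 for age (2628, at most 396), 2 of 80 for SAHA (1508, at most 3266), 1 of 80 for old SAHA against young (4696, at most 2580) and 3 of 80 for opposite changes (336, at most 2495). For exon part use, with limma diffSplice, 1 of 22 splits did in each case: CA1 age (1015, at most 5), CA1 SAHA (1778, at most 769), liver age (32, at most 4) and liver SAHA (30, at most 3). Tissue differences gave 1 of 50 for age (1908, at most 695) and 1 of 50 for SAHA (1416, at most 96). For the numbers of lists chance could not be excluded in CA1 for age (20 of 80 splits, 8 lists, at most 11) and SAHA (77 of 80, 3, at most 15), or in liver for age (11 of 80, 16, at most 19) and SAHA (72 of 80, 6, at most 20). Old SAHA against young gave 2 of 80 in CA1 (16, at most 16) and 3 of 80 in liver (19, at most 20). With no correction over the counts, chance is not excluded. In CA1 the number was 13 without old SAHA library 5 (splits not repeated without it), which several other splits reached.

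A library far from the others of its group was found for 70 of 481 group values, where chance gives about 1 in 20 groups (24.05). In CA1, in CPM with the next library in brackets: Old SAHA library 5 had high Ttr 7120 (26.1), H2-Eb1 30.5 (4.26), Hspa5 306 (265), Dnajc3 122 (94.8), Col3a1 15.3 (6.18), Ighm 162 (27.6), Aqp1 28.3 (0.941), Coch 32.3 (10.8), first principal component 52.0 (14.1). Old SAHA library 6 had high Lars2 1180 (467), Prr7 12.6 (6.30), Tpgs1 22.6 (12.5), Crlf2 10.4 (5.69), H1fx 12.3 (7.88), Map1s 49.9 (34.2), Trem2 33.4 (23.7). Old vehicle library 5 had high Oasl2 34.1 (6.80), Ifit3 24.8 (9.90), Lgals3bp 51.2 (28.4), Irf7 18.5 (6.97). Old vehicle library 3 had high Rnf152 13.3 (10.4), H2-DMa 16.9 (15), Opalin 47.9 (30.7). Single values were high Fos 26.5 (16.2) in young vehicle library 3, low Hdac2 79.5 (83.2) in old vehicle library 1, high Tap2 8.99 (7.53) in young vehicle library 1, low Pdia6 100.2 (110) in young vehicle library 8, high Prlr 11.4 (6.50) in young vehicle library 6, high Tnc 12.7 (6.73) in old vehicle library 6, low Ccdc117 21.5 (25.0) in old SAHA library 1. The first principal component had no unit.

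Liver libraries far from the others of their group were as follows. Old vehicle library 5 had high Clec4n 49.1 (14.4), Ly6a 211 (20.9), Clec12a 93.7 (20.4), Wfdc17 118 (32.5), Nlrc5 72.2 (52.7), Psmb9 74.6 (40.0), Ciita 9.69 (3.8), Ifi27 577 (258), Usp18 53.7 (29.1), C1qa 394 (102), C1qc 307 (87.4), Ccl5 37.2 (12.2), Cd3g 6.14 (2.22), Tubb2a 22.7 (11.1), B2m 3148 (2509), Cd4 34.2 (7.31) and low Ndufv1 148 (178). Old vehicle library 7 had high Lcn2 265 (73.2), Mt2 332 (39.8), Egr1 104 (39.3), Cyp2b9 7.13 (1.45), Rab11fip4 5.53 (3.52), C3 9389 (7140), Hsp90aa1 22.2 (16.6), Hspa8 218 (164), Trf 2888 (2226). Old SAHA library 2 had high Dbp 50.9 (21.9), Rgs16 44.0 (13.1), Nr1d1 29.0 (15.2), Hdac11 64.9 (49.5), G6pc 712 (269). Young vehicle library 1 had high Ntrk2 2.37 (1.01), Hdac11 72.8 (55.5) and low Clock 19.6 (38.3), Cry1 21.7 (32). Old SAHA library 3 had high Cd4 16.5 (4.88) and low Abcb11 301 (419). Single values were high Mup17 144 (50.3) in old vehicle library 4, high Itgax 1.17 (0.793) in young vehicle library 2, high Marco 143 (14.5) in old SAHA library 6.

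Effects differed between the tissues by the test of the difference for 1908 genes with age and 1416 with SAHA. Liver minus CA1, in log2 with the adjusted p of edgeR in brackets, these included for age Wasf1 -1.53 (2.07e-07), Hsph1 -1.22 (0.00135), Prex1 1.70 (1.60e-09), Cdh19 6.01 (3.13e-09), Jchain 3.41 (0.00363), C4b -2.22 (4.58e-07), Zfp788 1.07 (2.13e-08) and for SAHA Clint1 0.59 (4.51e-06), Hdac5 0.74 (0.00196), Rab11fip4 2.16 (6.05e-06), Nr1d1 -1.54 (0.00124), Kifc3 1.42 (6.97e-07), Gtf3c1 0.55 (2.74e-05), Lad1 2.07 (8.78e-06).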

How the results depend on the processing

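Of 2606 values that planned and later settings gave for 208 passing genes, 2193 kept direction and side of the threshold, 395 kept direction only and 18 changed sign; for 46 genes that had not passed, 543 of 629 stayed as they were. Each of the 186 passing gene values stayed so with DESeq2, 177 of 178 with DESeq2 size factors (the median fold change moved by at most 0.00769), 170 of 170 under the stricter filter and 163 of 178 with no filter, where more genes are adjusted for. Leaving out 1 library kept 2183 of 2427 values and changed the sign of 0 of the passing genes. At a simulated fold of 1.5 CA1 recovered 40 of 50 genes for age and liver 18 of 50, at similar library totals, so changes of that size can have been missed in liver; depth itself was not varied. The immune, clock, red blood cell and choroid plexus scores, the GC trend, the empty share of exon reads, sums of exon parts leaving out CA1 old SAHA libraries 3 and 5 together and leaving out old vehicle library 5 from the lists were chosen after seeing the data. No planned setting was left out.

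Passing genes numbered, in the results above, CA1 age 891, CA1 SAHA 913, CA1 old SAHA against young 587, CA1 opposite changes 209, CA1 age exon use 1262, CA1 SAHA exon use 1673, liver age 2628, liver SAHA 1508, liver old SAHA against young 4696, liver opposite changes 336, liver age exon use 61, liver SAHA exon use 54, age tissue difference 1908, SAHA tissue difference 1416. Numbers over 1.5 times apart, whose cause was not tested unless stated, were as follows. DESeq2 gave CA1 age 1349, CA1 SAHA 1528, CA1 old SAHA against young 974, CA1 opposite changes 428. No filter gave CA1 SAHA 564, CA1 opposite changes 104. Only the 2 groups compared gave CA1 age 1603, CA1 SAHA 457, CA1 old SAHA against young 333. Voom with quality weights gave CA1 age 2988, CA1 SAHA 2294, CA1 opposite changes 1170, liver opposite changes 549. The surrogate variable gave CA1 age 1560, liver age 994, liver old SAHA against young 375, CA1 opposite changes 362, liver old SAHA against young lists 9. The Simes method gave CA1 SAHA exon use 830, liver age exon use 21, liver SAHA exon use 24, and limma diffSplice liver age exon use 32, liver SAHA exon use 30. An estimated correlation, by its wider variance, gave CA1 age lists 0, CA1 SAHA lists 0, CA1 old SAHA against young lists 0, liver age lists 0, liver SAHA lists 0, liver old SAHA against young lists 0, and fry CA1 old SAHA against young lists 10, liver age lists 7, liver SAHA lists 1 (a lower one). Old vehicle libraries split between the fold changes gave CA1 covariance -0.0164, liver covariance -0.0165 (against -0.0259 and -0.0544).

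Of the settings chosen after seeing the data, the GC trend removed gave CA1 age 547, CA1 SAHA 23, CA1 opposite changes 9, CA1 SAHA lists 6. The red blood cell score gave CA1 age 1637, CA1 old SAHA against young 61, CA1 opposite changes 432 and kept 393 of the 913 CA1 SAHA genes (927 passing), and the choroid plexus score CA1 age 1340, CA1 old SAHA against young 243. The clock gene score gave liver age 121, liver SAHA 0, liver opposite changes 0, liver SAHA lists 10, and the immune cell score liver age 372, liver old SAHA against young 119, liver opposite changes 189. Without CA1 old SAHA libraries 3 and 5 the numbers were CA1 age 1499, CA1 SAHA 581, CA1 old SAHA against young 366. Without libraries of an empty share over 10% they were liver SAHA 451, liver old SAHA against young 739, liver opposite changes 153. With the empty share in the model, and with sums of exon parts, they were CA1 opposite changes 385 and CA1 opposite changes 351. In CA1 the exon tables matched the gene table of their own number in only 11 of 20 libraries, so the empty share was set to other libraries in part and its CA1 values decide little. Leaving out 1 library in turn gave CA1 age 445 to 1302, CA1 SAHA exon use 973, CA1 opposite changes 55 to 205, CA1 old SAHA against young 334 to 805, CA1 SAHA 278 to 1351, liver age 1671 to 2738, liver SAHA 975 to 2166.

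Signs changed, as log2 fold changes whose cause was not tested, for CA1 SAHA Ttr -3.04, H2-Eb1 -1.09, Col3a1 -0.56, Ighm -1.05, Aqp1 -0.93, Coch -0.35 with the red blood cell score, H2-Eb1 -0.13, Ighm -0.16 with the surrogate variable, H2-Eb1 -0.35, Col3a1 -0.37, Ighm -0.0291 without libraries 3 and 5, Ighm -0.0814 with voom, Ighm -0.11 without old SAHA library 5, Ighm -0.19 with sums of exon parts, Ighm -0.30 with the choroid plexus score, Slc32a1 0.0417 with the GC trend removed. They changed for liver age Clec4n -0.90, Ly6a -0.44, Clec12a -0.80, Wfdc17 -0.43, H2-DMb1 -0.46, Ciita -0.19, C1qa -0.74, C1qc -0.77, Dcn -0.22, Alas2 0.20, Itgax -0.24 with the immune cell score, Arntl 0.54 with the clock gene score. They changed for liver SAHA Arntl -0.85, Dbp 0.11, Rgs16 0.23, Hdac5 -0.20, B2m 0.0107, Irf9 0.0752, Hsp90aa1 -0.22, Hspa8 -0.12, Uqcrc2 0.0338, Birc5 0.0126, Alas2 0.33, Marco -1.64, Saa2 -0.64 with the clock gene score, Ciita -0.27, Ms4a1 -0.16 with the surrogate variable, Ciita -0.17, Ms4a1 -0.0380 with the empty share in the model, Ciita -0.43, Ms4a1 -0.64 without libraries of a high empty share, Cd4 0.48 without old vehicle library 5. Over all libraries left out in turn, Ighm (CA1 SAHA) ran from -0.11 to 1.38 and Cd4 (liver SAHA) from -1.63 to 0.48.

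The replicate number as a block gave CA1 old SAHA against young 265, liver age 1305, liver SAHA 478, liver old SAHA against young 2728, liver opposite changes 125, liver SAHA exon use 27, CA1 age lists 5, CA1 SAHA lists 5, and within each tissue age tissue difference 877, SAHA tissue difference 731. Libraries of the same number correlated above 0.1 in 8 of 18 CA1 pairs and in 1 of 19 liver pairs, and their own number was the best match in 1 and 0, so the numbers were not treated as pairs.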

Other observations

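Gene families were counted; they were chosen after their values were seen, and no test of an explanation was run on them. In old CA1, 13 of 22 clustered protocadherin beta (Pcdhb) genes, which encode neuronal adhesion proteins, were higher than in young (median 0.43, the same number with the GC trend removed or other size factors), and 0 differed with SAHA. In old liver, 8 of 19 major urinary protein (Mup) genes were lower with age (median -1.33) and 3 were lower with SAHA (median -0.86, 1 with the GC trend removed). With SAHA, 4 of 9 alpha- and beta-tubulin genes were higher in liver, and 6 of 38 proteasome (Psm) genes were lower (1 with the GC trend removed).

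Genes that rose with age in both tissues, chosen after their values were seen, included Tap1 (1.11 in CA1, 1.5 in liver), Trim30d (1.23, 2.01), Naip2 (0.81, 1.26), Xaf1 (0.79, 1.84), Csf3r (0.81, 2.73) and Cd37 (0.75, 2.11), and Tsc22d3 fell in both (-0.46, -1.15). With SAHA, Sult1a1 rose in both (0.95, 0.63), while Kifc3 (-0.33, 1.05), Chpf (-0.58, 0.99) and Zdhhc8 (-0.37, 0.45) fell in CA1 and rose in liver. With the GC trend removed, Chpf passed in CA1 (-0.44) and Kifc3 and Zdhhc8 did not.

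Library measures were compared between groups. Old vehicle libraries of CA1 held 26.4 ± 3.32 M counts, young vehicle 22 ± 3.58 M and old SAHA 22.4 ± 2.62 M (exact tests, p = 0.0393 and p = 0.0455, adjusted p = 0.136). The 10 most counted liver genes held 17.1 ± 1.55% of counts in old vehicle, 19.8 ± 1.56% in young vehicle and 18.9 ± 0.861% in old SAHA (exact tests, p = 0.00816 and p = 0.0103, adjusted p = 0.0615). Hbb-bs was above its old vehicle mean in every old SAHA library of CA1 (35.7 to 85.3 against 19.8 ± 3.98 CPM). Hba-a1 and Hba-a2 were not. In liver, GC slopes were 0.0517 ± 0.0361 in old SAHA, -0.0409 ± 0.0424 in old vehicle and -0.0212 ± 0.0726 in young vehicle (exact test, p = 0.00124, adjusted p = 0.00497 for SAHA, p = 0.587 for age), and 1208 of the 1508 SAHA genes passed with the trend removed.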
